A study of Mus musculus with 12 samples.

How the data were processed

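The 4 10x Genomics wells of CD90.2-positive cells sorted by Kaede colour from MC38 tumours were analysed, each with a gene expression library (GEM-X 5' version 3, per the labels' protocols), a hashtag library and a TCR library. The deposited matrices hold raw UMI counts per gene or hashtag and cell barcode, written by Cell Ranger 8.0.1 per the file headers, on the mouse build mm39 per the submitters' processing notes. The deposited TCR tables hold counts of reads and UMIs per assembled contig, from filtered contigs of Cell Ranger 8.0.1 per the submitters' processing notes. Barcodes were called as cells before deposit, and further filters by the authors are not given in the sources used here. No genome was used, so genes are given by the symbols and identifiers of the deposited matrices, without coordinates. The wells held 692 and 1691 barcodes (NT day 1, RT day 1 and NT day 3, replicates 1 and 2) and 148 and 285 barcodes (RT, FTY720 and RT with FTY720 at day 3).

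Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left out 76 barcodes and kept 666, 1651, 143 and 280 per well, at medians of 20920, 20200, 19520 and 17860 UMIs. A cell was given to a sample where its top hashtag had at least 20 UMIs and at least 3 times the next. HTODemux (Seurat 5.3.0, positive quantile 0.99) had been planned as the main call. It was exchanged with that rule, which had been planned as its alternative, after the hashtag counts were seen and before any expression comparison. The reason was that the 597 barcodes that HTODemux did not call singlets had medians of 8 UMIs for the next hashtag and 7318 for the top one. Over all 2816 barcodes the next hashtag stood at a median of 0.0513% of the top one. HTODemux needed 1 UMI added to every hashtag count. Colours follow the hashtag names in the deposited matrices. In the replicate 2 wells these conflict with the tag numbers of the labels, which were matched to tag sequences through the replicate 1 names. The matrices' colours were chosen after the names were seen and before any expression comparison, and the label colours were run as an alternative. No doublet caller was run. The hashtag rule left out 0 cells, so it removed no doublet between samples, and 90 cells (3.29% of those kept) with 2 or more productive TCR beta chains were kept and left out as an alternative.

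Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 were used (scanpy 1.11.5, leidenalg 0.10.2). Clusters were named from markers fixed before the data were examined, as were the groups, designs, gene lists and the rule for named genes. A marker counted with a fold of at least 1.25 in at least 10% of a cluster's cells, and a name needed at least 3 markers. The 3 mixed clusters, of 280 cells, led by cell cycle (65 cells), p53 target (54) and interferon genes (161), were split cell by cell on lineage markers, a rule chosen after the data were seen. That rule returned the class of their cluster for 89.2% of cells of named clusters. Its class profiles came from these same cells, so its accuracy in the mixed clusters is not known. Leaving out the mixed clusters was an alternative. In names, cluster 0 was led by Klrh1 and Klre1, 1 by Nrgn and Rgs16, 5 by Gzmk and Ccl5, 12 by Il2 and Ccl3, 14 by Gzma and Cd7, 7 by Foxp3 and Il1rl1, 8 by Areg and Tnfrsf4, and 9, which held 56.9% of green and 72.3% of red CD4 conventional-like cells, by Ramp3 and Cd40lg.

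Raw counts were summed per tumour pool, colour and class, with at least 5 cells per sum, and tested with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. Red against green used the tumour pool as a block. Radiation was tested within each colour over 3 strata (day 1, day 3, day 3 with FTY720) with the stratum as a term, at day 1 with a mean per condition, and at day 3 with both colours summed, because the day 3 RT and FTY720 wells held few cells. FTY720 was tested as the mean of both FTY720 conditions against that of NT and RT at day 3. Differences between effects were tested as contrasts in those fits. CPM are TMM-scaled, and log2 fold changes are edgeR's with their SE. Where a pool was left out and a condition kept 1 pool, that pool was assumed to vary like the others. Genes with no count in one group were given no fold.

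Fixed lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of one contrast: Treg core, tumour effector Treg, naive and lymph node homing, migration receptors, exhaustion, cytotoxic effector, p53 targets, interferon-stimulated, cell cycle, early activation, dissociation and heat shock, IL2 and STAT5, and myeloid genes. Named genes were the 10 largest changes in each direction among those past the threshold with one direction in both replicates (for red against green, in at least 9 of 12 or 6 of 8 pools), up to 6 members per list, and genes set in advance. TCR, immunoglobulin, mitochondrial, ribosomal and unnamed gene models were left out of the first group, and the text gives those with a known role.

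Shares were taken of all T-lineage cells in pools with at least 10 such cells per colour and compared with two-sided exact sign-flip or within-stratum (216 arrangements) permutation tests. A clone was a TCR beta CDR3 nucleotide sequence, found in 2514 cells as 1933 clones. Intervals are 95% and cover counting error only.

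The replicate number marks a shared 10x well within each set of 3 conditions, by the sample titles, so it pairs those conditions. Deviations from the condition means correlated between conditions of the same wells at r = 0.0265 to 0.0934 (median 0.0411, 6 pairs) in CD8-like cells and at −0.125 to 0.0758 (median −0.0412) in Treg-like cells, against −0.0485 to 0.0917 and −0.0774 to 0.153 across wells (9 pairs). On simulated counts with 200 changed genes, edgeR recovered 55.4% of 2-fold and 94.8% of 4-fold changes in red against green Treg-like cells (8209 genes), 85.3% and 97.9% in CD8-like cells (8251 genes), and 67.0% and 99.0% for radiation in green CD8-like, 73.2% and 95.7% in red CD8-like, 7.50% and 68.5% in green Treg-like and 66.0% and 96.8% in red Treg-like cells. For FTY720 it recovered 39.6% and 77.9% in Treg-like and 59.8% and 92.9% in CD8-like cells. The simulated counts held no effect of pool, stratum or well, and the percentages cover the changed genes that passed the filter. Recovery in the real data can therefore be lower.

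Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, at least 10 cells per sum or 20 per share, marker gates per cell in place of clusters, HTODemux, cells with 2 beta chains left out, replicate and well terms, 1 colour or both summed, other clone definitions and each pool left out. R 4.3.3, Python 3.11.15, data.table (1.17.8), Matrix 1.6.5, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.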

Results

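Single-cell RNA, hashtag and T cell receptor (TCR) sequences were measured in CD90.2-positive cells sorted from MC38 tumours, a mouse colon carcinoma line, grown in Kaede mice, whose cells carry a green protein that violet light turns red. The tumour-draining lymph node was photoconverted on day 14, so that red cells found in the tumour had been in that node and arrived afterwards, and green cells had not been converted. Tumours then received 12 Gy of radiation (RT) or none (NT) and were collected 24 h later (day 1) or 72 h later (day 3). Radiation effects below compare cells of irradiated and unirradiated tumours. Which red cells were in the tumour at irradiation was not measured. FTY720, a sphingosine-1-phosphate receptor modulator that holds lymphocytes in lymphoid tissue, was given on day 15 to some animals collected at day 3. The 6 conditions were NT and RT at day 1 and NT, RT, FTY720 and RT with FTY720 at day 3, each in 2 replicates of 4 pooled tumours, so that 12 tumour pools gave 24 hashed samples of red or green cells. NT day 1, RT day 1 and NT day 3 shared a 10x well in each replicate, and the other 3 conditions shared another, which places RT against NT at day 3 in different wells.

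Of 2816 deposited barcodes, 2740 were kept, with 17 to 322 cells and 337319 to 7891316 UMIs per hashed sample. Clusters were named from marker genes, which gave 1302 CD8-like, 590 Treg-like (regulatory T), 407 CD4 conventional-like, 380 naive CD8-like and 61 naive CD4-like cells. Tag sequences were matched to the tag numbers in the sample labels through the replicate 1 names. Replicate 1 therefore differs from the labels in 0 of 12 hashed samples by construction. In the replicate 2 wells the hashtag names in the deposited matrices exchange red and green relative to this match for 12 of 12. The label colours below rest on the same match. Colours below follow the matrices, and comparisons that sum both colours do not depend on this choice. Under the matrices' names the red against green differences of the replicate 1 pools and of the replicate 2 pools correlated with Pearson r = 0.386 across genes in CD8-like cells, where genes are not independent replicates. P-values measure the spread between these pools of tumours. For edgeR that spread is estimated in part from other genes, since the reported fits leave 3 to 11 residual degrees of freedom per gene. Chance alone would put about 0.05 of the genes tested at an unadjusted p below 0.05, so counts at that level are no sign of missed changes by themselves.

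The first question was which T cells arrived from the draining node. CD4 conventional-like cells made up 10.7% ± 3.76 of red and 20.7% ± 6.57 of green T cells (SD, n = 12 pools) and were lower in red in all 12 pools (exact sign-flip permutation test, two-sided, p = 0.000488, the smallest this design can give; adjusted over 5 classes p = 0.00244). Treg-like cells made up 25.03% ± 7.93 of red and 15.8% ± 5.42 of green T cells and were higher in red in 9 of 12 pools (exact permutation p = 0.0200, adjusted p = 0.0501, past the threshold only before adjustment). CD8-like cells made up 48.4% ± 11.1 of red and 52.1% ± 9.85 of green cells (exact permutation p = 0.237). Naive CD8-like cells stood at 13.9% ± 10.2 and 9.92% ± 5.98 (exact permutation p = 0.274), and naive CD4-like cells at 1.95% and 1.49% (exact permutation p = 0.500). Radiation did not change the Treg-like share past the spread of the pools. In green cells it was 14.8% ± 5.30 in irradiated and 16.8% ± 5.85 in unirradiated tumours (n = 6 pools each, exact permutation p = 0.583). In red cells it was 25.9% ± 7.38 and 24.1% ± 9.06 (n = 6 each, exact permutation p = 0.685). These differences changed sign without NT day 1 replicate 2 (0.275 and −1.46 percentage points), in green cells also without RT day 3 replicate 2 (0.429) and in red cells also without RT day 1 replicate 2 (−1.52). The enrichment and the sort on CD90.2 can set these shares. With the label colours the Treg-like difference of 9.27 points became −2.18.

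**Figure D1:**
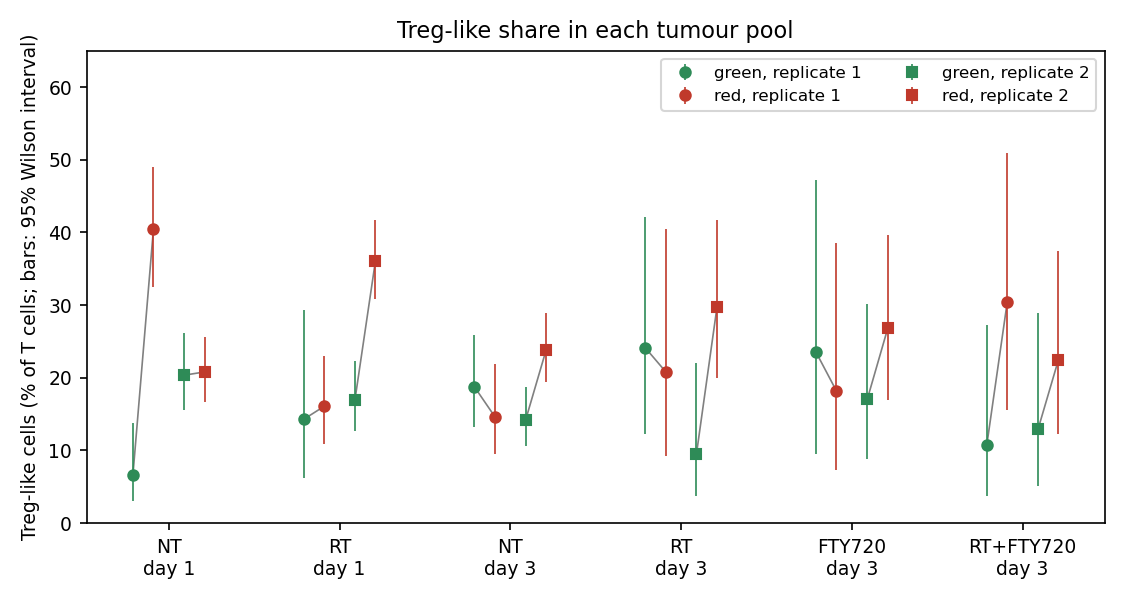
Treg-like cells as a percent of T cells (vertical axis) in red and green cells of each of the 12 tumour pools, by condition (horizontal axis), with 95% Wilson intervals that cover counting error only. The red share lies above the green share in 9 of the 12 pools.

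Red Treg-like cells carried more of the lymph node homing receptor Ccr7 and of early TCR response genes than green Treg-like cells of the same tumours, and less of the inhibitory receptors Lag3 and Pdcd1. Ccr7 (ENSMUSG00000037944) stood at 56.7 ± 54.5 CPM (UMI counts scaled to a common total) in red and 6.004 ± 5.96 CPM in green cells (SD, n = 8 pools), a log2 fold change of 2.48 ± 0.33 (SE). Nr4a1, a nuclear receptor induced by TCR signalling, stood at 523 ± 194 against 222 ± 128 CPM and was higher in red in 8 of 8 pools (log2 1.29 ± 0.20). Lag3, an inhibitory receptor that binds MHC class II, stood at 66.7 ± 60.8 against 262 ± 65.2 CPM and was lower in red in 8 of 8 pools. Foxp3, the lineage transcription factor, was measured at 805 ± 134 against 735 ± 81.3 CPM and did not pass (log2 0.12 ± 0.10), nor did Ccr8, a chemokine receptor of tumour Treg cells, at 0.61 ± 0.37.

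In all, 102 genes were higher and 64 lower in red Treg-like cells among 8762 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05; sums of 5 to 105 cells). Of the early activation genes, 3 of 13 measured members rose and the rest did not pass (8 higher and 1 lower adjusted over the list alone), with a list median of 0.79. The examples are Nr4a1, Nr4a3 (1.10 ± 0.20) and Irf8, a transcription factor of the interferon regulatory family (1.12 ± 0.20). Of the naive and lymph node homing genes, 2 of 12 rose (3 adjusted over the list alone), Ccr7 and the transcription factor Klf3 (1.28 ± 0.23). Of the exhaustion genes, 3 of 13 fell (1 higher and 6 lower adjusted over the list alone): Lag3, the inhibitory receptor Pdcd1 (−0.91 ± 0.22) and Entpd1, an ectonucleotidase that degrades ATP (−0.73 ± 0.16). Camera tests of these 3 lists held with an estimated correlation. Of the tumour effector Treg genes 2 of 20 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.319), Entpd1 again among them, with Gzmb, which encodes the cytotoxic protease granzyme B (0.66 ± 0.11), and the costimulatory receptor Tnfrsf4 (0.47 ± 0.10) higher. Ccr4, a chemokine receptor for CCL17 and CCL22, was the member of 18 migration receptors that rose (1.18 ± 0.26; camera adjusted p = 0.319). Of the p53 targets, the cell cycle inhibitor Cdkn1a was lower (−0.85 ± 0.22), 1 of 22, and the list's call at a preset correlation was lost, with adjusted p = 0.554 with an estimated correlation. The chaperone genes Hspe1 (0.90 ± 0.16) and Hsp90aa1 (0.76 ± 0.15) rose, 2 of 14 dissociation and heat shock genes, whose list median was 0.13. No Treg core gene passed in 12 measured (camera adjusted p = 0.319). Different clusters held most of the class: cluster 11, led by Frmd5, Il10 and Itgb8, held 68.2% of green cells, and clusters 8 and 7, led by Areg and Foxp3, held 46.5% and 30.9% of red cells. The count was 31 without RT day 1 replicate 2, 51 without NT day 1 replicate 2, and 91 and 100 without replicate 1 of NT and of RT at day 1. It was 40 with HTODemux hashtag calls, which had been planned as the main call, and 0 with the label colours. Of 21 named genes that passed, 11 passed in each of the 8 fits with a pool left out, among them Ccr7, Nr4a1, Nr4a3, Irf8, Klf3, Gzmb and Hspe1. Lag3 did not pass in 6 of the 8 fits with a pool left out (all but those without replicate 1 or 2 of NT day 3) and Pdcd1 in 5 (all but those and the one without FTY720 replicate 2).

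**Figure D2:**
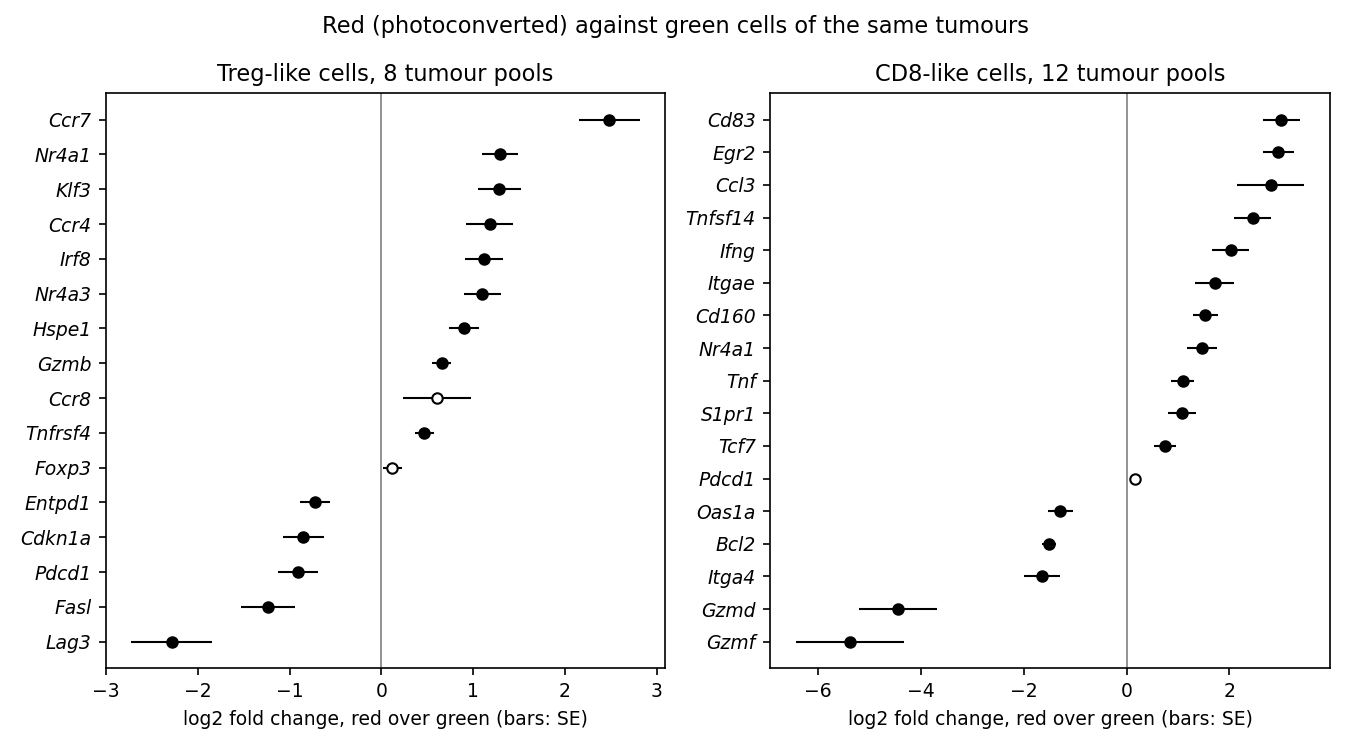
Log2 fold change of red against green cells (horizontal axis, bars are SE) for named genes (vertical axis) in Treg-like cells of 8 tumour pools and CD8-like cells of 12, filled where the adjusted p was below 0.05 and open where not. Ccr7 at 2.48 and Lag3 at −2.29 bound the Treg-like panel's TCR response and receptor genes, and the granzyme genes Gzmf at −5.38 and Gzmd at −4.44 lie lowest in the CD8-like panel.

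Red CD8-like cells carried more of the transcription factor Egr2 and of the cytokine genes Ifng and Tnf, and less of Bcl2 and of the granzyme genes Gzmd and Gzme, than green CD8-like cells of the same tumours. Egr2 (ENSMUSG00000037868) stood at 60.5 ± 29.6 CPM in red and 8.71 ± 9.65 CPM in green cells (SD, n = 12 pools), a log2 fold change of 2.95 ± 0.30 (SE), higher in 11 of 12 pools. Ifng, the type 2 interferon gene, stood at 3033 ± 2194 against 667 ± 332 CPM and was higher in red in 12 of 12 pools. Bcl2, which blocks apoptosis, stood at 246 ± 93.5 against 675 ± 202 CPM and was lower in red in 12 of 12 (−1.51 ± 0.14). Gzmf, a granzyme gene, stood at 13.8 ± 35.0 against 258 ± 273 CPM (−5.38 ± 1.05). Pdcd1 did not pass (0.16 ± 0.10).

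Of 8625 genes tested, 432 were higher and 319 lower in red CD8-like cells (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05; sums of 9 to 176 cells). Of the early activation genes, 9 of 14 rose and the rest did not pass (12 adjusted over the list alone), with a median of 1.28, among them Egr2, Ifng, Nr4a1 (1.46 ± 0.29) and Nfkbid, a regulator of NF-kappaB (1.38 ± 0.17). The camera call was lost, with adjusted p = 0.0623 with an estimated correlation, and fry's directional test gave an adjusted p of 0.00111. Of 15 dissociation and heat shock genes 1 was higher, and the list median was 0.13 (camera adjusted p = 0.199). Of the cytotoxic effector genes, 4 of 19 rose and 3 fell (9 and 4 adjusted over the list alone). The chemokine gene Ccl3 (2.80 ± 0.65), Ifng (2.02 ± 0.36) and Tnf, an inflammatory cytokine gene (1.09 ± 0.22), were higher, and Gzmd (−4.44 ± 0.76), Gzme (−5.40 ± 0.84) and Gzmf lower. These 3 granzyme genes are close paralogs, so that counts can be split between them. That list's median was 0.32 and its mean −0.25, and its call was lost, with adjusted p = 0.310 with an estimated correlation. Of the exhaustion genes, 4 of 15 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.403 with an estimated correlation), with Cd160, a receptor for HVEM (1.53 ± 0.25), and Lag3 (0.66 ± 0.16) higher and the receptors Cd244a (−1.93 ± 0.43) and Cd38, an NAD-consuming ectoenzyme (−1.43 ± 0.28), lower. Of the naive and homing genes, 4 of 12 rose (5 and 1 lower adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), among them the egress receptor S1pr1 (1.08 ± 0.28), Il7r, the interleukin-7 receptor (0.79 ± 0.20), and the transcription factor Tcf7 (0.75 ± 0.21). Of 25 interferon-stimulated genes, 3 fell (5 adjusted over the list alone; adjusted p = 0.632 with an estimated correlation), among them the antiviral genes Oas1a (−1.28 ± 0.25) and Oasl2 (−1.08 ± 0.25) and Stat2, a signal transducer of type I interferon (−0.64 ± 0.19). Without the cells of the 3 mixed clusters Oasl2 stood at 0.00 and this list's median at 0.16. Itgae, the integrin of epithelial retention, was higher (1.72 ± 0.38) and Itga4, a subunit of the VCAM1-binding integrin, lower (−1.65 ± 0.35). Of markers of other cells, Cd74, the MHC class II chaperone, was higher (1.46 ± 0.39), and Fcer1g (−2.83 ± 0.59) and the immunoglobulin gene Ighm (−0.89 ± 0.21) lower. Clusters 0 and 5 held 38.8% and 35.1% of green cells, and clusters 1, 0, 5, 12 and 14 held 22.3%, 19.5%, 18.3%, 17.1% and 15.0% of red cells. Clusters 12 and 14 held 14.4% and 13.4% of CD8-like cells in NT day 1, and 5.30% and 2.53% in NT day 3. Colour effects by day were not tested. The count was 337, 362, 401 and 494 without RT day 1 replicate 2, NT day 1 replicate 2, NT day 1 replicate 1 and NT day 3 replicate 2, and 1 with the label colours. Of 30 named genes that passed, 19 passed in every fit with a pool left out, among them Egr2, Ifng, Tnf, Bcl2, Gzmd, Gzme, Itga4 and Cd38. Of these 12 fits, Cd74 did not pass in 10, Stat2 in 9, Tcf7 in 8, Il7r in 5, Ccl3, Gzmf and S1pr1 in 4 each and Cd244a in 3. The fits without NT day 1 replicate 1, NT day 1 replicate 2 or RT day 1 replicate 2 are among these for each gene. Itgae and Oasl2 did not pass without RT day 1 replicate 2.

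Red CD4 conventional-like cells carried more of the genes Tcf7 and S1pr1 and less of the chemokine gene Ccl4 than green ones. Tcf7 stood at 493.4 ± 209 CPM in red and 212 ± 83.8 CPM in green cells (SD, n = 8 pools) and was higher in 8 of 8 pools (1.15 ± 0.18), and S1pr1 was higher by 1.02 ± 0.17. Ccl4, which recruits T cells and monocytes, was lower in 8 of 8 pools (−2.14 ± 0.35), and Csf1, the macrophage growth factor, in 7 of 8 (−1.95 ± 0.30). Of 7114 genes, 11 were higher and 6 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the naive and homing genes 2 of 11 rose (6 adjusted over the list alone), with a median of 0.81 and a camera call that held with an estimated correlation. Of the cytotoxic effector genes 2 of 14 fell (4 adjusted over the list alone), Ccl4 and Fasl, the ligand of the death receptor Fas (−0.95 ± 0.19), with a median of −1.09, and the call was lost, with adjusted p = 0.0514 with an estimated correlation. Of 10 Treg core genes 2 rose (adjusted p = 0.260 with an estimated correlation): Ctla4, an inhibitory receptor of B7 ligands (0.72 ± 0.15), and Il10, an immunosuppressive cytokine gene (101 ± 185 against 0.419 ± 0.844 CPM, higher in 4 of 8 pools). The count was 11, 10, 7 and 32 without NT day 1 replicate 1, RT day 1 replicate 1, RT day 1 replicate 2 and RT day 3 replicate 2, 4 with HTODemux and 0 with the label colours. Tcf7, Csf1 and Ccl4 passed in every fit with a pool left out that gave a value. S1pr1 did not pass without RT day 1 replicate 2. Fasl did not pass in 6 of 8 (it passed without NT day 1 replicate 2 or RT day 3 replicate 2). Ctla4 did not in 5 of 8 (without replicate 1 or 2 of NT day 1, replicate 1 of NT day 3, or replicate 2 of RT day 1 or RT with FTY720). Il10 did not in 3 of 6 (without replicate 1 of NT day 1 or RT day 1, or RT with FTY720 replicate 2).

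TCR sequences were compared between the colours. A mean of 0.874% ± 1.5 of red cells carried a TCR beta sequence found in green cells of the same tumours, against 0.0274% ± 0.0950 in green cells of other mice in the same well (SD, n = 12 pools; exact sign-flip permutation test, two-sided, p = 0.0313). Shared sequences were seen in 6 of 12 pools and in 1 to 4 red cells of each. The p-value rose above 0.05 without any of these 6 pools (NT day 1 replicate 2, both NT day 3 replicates, both RT day 1 replicates and RT with FTY720 replicate 1), since 5 such pools cannot give one below 0.0625, and leaving out the last of them lowered the difference from 0.847 to 0.445 percentage points. That difference was 0.489 with at least 20 cells, 0.652 with alpha and beta chains together, 0.616 with Cell Ranger clonotypes and 0.287 with HTODemux, each no longer past 0.05. The probability that a pair of cells of one pool shared a TCR beta sequence was 1.61% ± 2.43 in red and 0.714% ± 0.781 in green cells (n = 12 pools, exact permutation p = 0.212), and that difference of 0.895 points was 0.258 without RT with FTY720 replicate 1.

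Green CD8-like cells of irradiated tumours carried more of p53 targets and some interferon-stimulated genes, and less of some mitotic genes. Cdkn1a (ENSMUSG00000023067), which encodes the p53-induced cell cycle inhibitor p21, stood at 156 ± 30.5 CPM in irradiated and 10.9 ± 8.15 CPM in unirradiated pools (SD, n = 6 each), a log2 fold change of 3.53 ± 0.31 (SE). Ccng1, the p53 target cyclin G1, stood at 236 ± 85.6 against 71.2 ± 16.7 CPM. Ifi204, an interferon-inducible DNA sensor gene, stood at 192 ± 151 against 4.44 ± 4.01 CPM (5.22 ± 0.63). Mki67, the proliferation marker Ki-67, stood at 38.2 ± 35.6 against 166 ± 104 CPM (−1.97 ± 0.35). Over the day 1, day 3 and day 3 FTY720 strata, 174 genes rose and 104 fell of 7389 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the p53 targets, 9 of 18 rose and the rest did not pass (14 adjusted over the list alone), with a median of 0.97 and a camera call that held with an estimated correlation. They included the apoptosis genes Bax (1.05 ± 0.19) and Bbc3 (1.97 ± 0.38) and Phlda3, an inhibitor of AKT (4.04 ± 0.64), and Mdm2, which targets p53 for degradation, did not pass (0.35 ± 0.20). Of the cell cycle genes, 7 of 18 fell (15 adjusted over the list alone), with a median of −1.76 and adjusted p = 0.0547 with an estimated correlation. Examples are Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (−3.33 ± 0.40), the kinetochore gene Cenpf (−3.06 ± 0.55) and Birc5, which encodes survivin (−2.23 ± 0.49). Of the interferon-stimulated genes, 5 of 25 rose (25 adjusted over the list alone), with a median of 1.54 and adjusted p = 0.225 with an estimated correlation. Oasl2 (2.53 ± 0.52) and Slfn5, a Schlafen family gene (2.49 ± 0.45), rose, and Isg15, a ubiquitin-like interferon effector, did not pass (2.05 ± 0.64). Hif1a, the hypoxia-inducible transcription factor (1.45 ± 0.24), Il7r (1.29 ± 0.31) and the chemokine receptor Cxcr4 (1.20 ± 0.28) also rose. The call count was 68 and 71 without replicates 1 and 2 of NT day 3, 71 and 84 without those of RT day 3, 179 and 116 without those of FTY720, 161 and 110 without those of RT with FTY720, 157 without NT day 1 replicate 2, and 438 and 428 without those of RT day 1. RT and NT at day 3 lay in different wells. With a well term the count was 10 (p53 list adjusted p = 0.0887 with an estimated correlation). Without the mixed clusters, of which cluster 10 is led by p53 targets and 13 by interferon genes, it was 16. It was 139 with HTODemux and 0 with the label colours. Cdkn1a, Phlda3, Ccng1, Bax, Bbc3, Ube2c, Mki67, Hif1a and Ifi204 passed in each of the 12 fits with a pool left out. Il7r did not pass in 11 (all but the one without RT day 1 replicate 2), Birc5 in 8, Cxcr4 and Oasl2 in 7 each, Slfn5 in 4. Cenpf did not pass without RT day 3 replicate 1. RT day 3 replicate 2, NT day 3 replicate 1 and NT day 3 replicate 2 are among the pools whose absence ended the calls of Il7r, Birc5, Cxcr4, Oasl2 and Slfn5.

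Within wells at day 1, the p53 response of green CD8-like cells was measured against NT pools of the same well. Cdkn1a stood at 138 ± 38.8 against 9.11 ± 6.37 CPM (SD, n = 2 pools each; 3.74 ± 0.49) and Phlda3 at 51.9 ± 3.22 against 1.38 ± 0.645 CPM. Of 7823 genes, 7 rose and 1 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05): Cdkn1a, Phlda3, Ccng1 (1.88 ± 0.29), Bax (1.64 ± 0.26), Exoc4, of the exocyst (1.49 ± 0.22), Cox6b2, a cytochrome oxidase subunit (4.76 ± 0.79), and the ribosomal protein gene Rps19, which the naming rule leaves out and which was chosen after its values were seen, were higher and Ube2c lower (−3.21 ± 0.48). Of the p53 targets 4 of 19 rose (12 adjusted over the list alone), with a median of 0.85 and a camera call that held with an estimated correlation. Of the cell cycle genes 1 of 18 fell (7 adjusted over the list alone), with a median of −1.51 and adjusted p = 0.0571 with an estimated correlation. No interferon-stimulated gene of 25 passed, with a list median of 0.65 and adjusted p = 0.734 with an estimated correlation, and the list's call at the preset correlation, adjusted p = 0.0433, became 0.0704 with a replicate block. The block moved the naive and homing list from 0.0433 to 0.0607 and the dissociation list from 0.0591 to 0.0364 as well (0.492 with an estimated correlation). No gene passed (0) without NT day 1 replicate 1, NT day 1 replicate 2 or RT day 1 replicate 2, where 315 genes had an unadjusted p below 0.05 with all pools and DESeq2 called 13. The 315 genes are fewer than chance alone would give at that level among 7823 tested. Cluster 10, led by p53 targets, held 11.9% of CD8-like cells of both colours in RT day 1 and was absent from those of NT day 1. The count was also lower without the cells of the mixed clusters. These changes can include shifts between clusters.

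**Figure D3:**
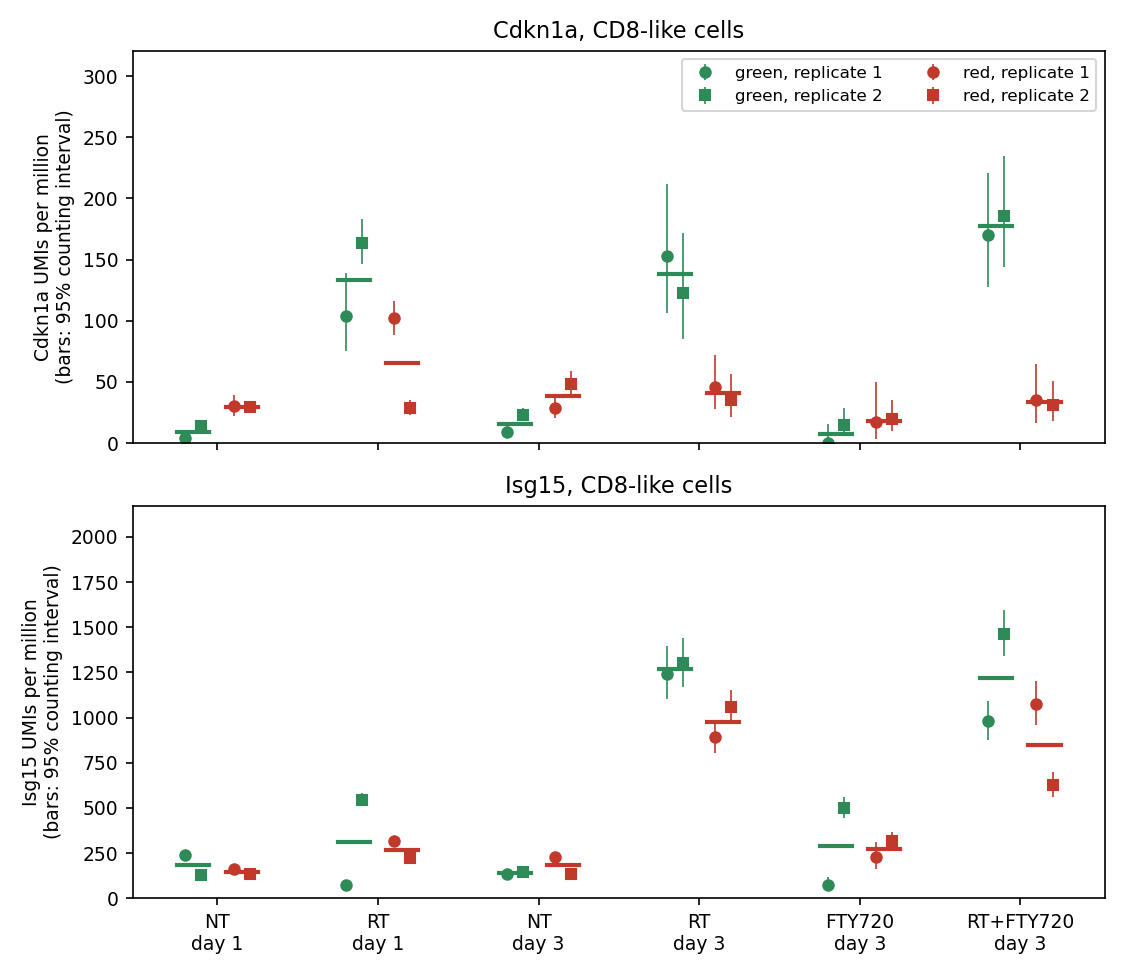
CPM without TMM scaling (vertical axes) of Cdkn1a and Isg15 in green and red CD8-like cells of each tumour pool by condition (horizontal axis), with 95% Poisson intervals for counting error only and a horizontal bar at each mean. Cdkn1a lies at 103.5 to 185 in irradiated green pools and at 0 to 22.8 in unirradiated ones, and Isg15 at 892 to 1300 in the RT day 3 samples.

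Red CD8-like cells of irradiated tumours carried more of the interferon-stimulated genes than those of unirradiated tumours. Isg15 (ENSMUSG00000035692) stood at 710 ± 375 CPM in irradiated and 202 ± 74.7 CPM in unirradiated pools (SD, n = 6 each), a log2 fold change of 1.65 ± 0.28 (SE), and Oasl2 at 59.6 ± 53.1 against 9.54 ± 10.5 CPM (2.29 ± 0.35). Cdkn1a stood at 46.9 ± 27.4 against 28.8 ± 10.3 CPM and did not pass (0.73 ± 0.33), nor did Gzmb (1.55 ± 0.31). Of 8968 genes, 66 rose and 2, Siglecf and Tacc2, fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the interferon-stimulated genes 11 of 25 rose and the rest did not pass (24 adjusted over the list alone), with a median of 1.43 and a camera call that held with an estimated correlation. They included the antiviral gene Ifit3 (1.61 ± 0.23) and the nucleic acid sensors Zbp1 (1.09 ± 0.16) and Ifih1 (1.36 ± 0.20). The count was 20 and 29 without replicates 1 and 2 of NT day 3, 35 and 24 without those of RT day 3, 41 without FTY720 replicate 2, 36 without RT with FTY720 replicate 1 and 139 without RT day 1 replicate 2. Isg15 did not pass in 7 of the 12 fits with a pool left out (it passed without either NT day 1 replicate or replicate 2 of NT day 3, RT day 1 or RT with FTY720), Siglecf in 8 and Tacc2 in 9. Oasl2, Ifit3, Ifih1 and Zbp1 passed in each. The count was 3 with HTODemux, 149 with the label colours, 12 without the cells of the mixed clusters and, with a term for the well, 0 by edgeR (846 genes had an unadjusted p below 0.05 without that term, and DESeq2 called 262). With the well term the interferon list had adjusted p = 0.0800 with an estimated correlation. Within wells at day 1 edgeR called 0 genes in red CD8-like cells and DESeq2 0, with 206 at an unadjusted p below 0.05, and 3 passed without RT day 1 replicate 2. These 206 are fewer than chance alone would give. Of the interferon list 9 of 25 were higher within wells at day 1 when adjusted over the list alone. Its median was 0.77, with camera adjusted p = 0.139 with an estimated correlation. Cdkn1a stood at 65.3 against 29.4 CPM (1.13 ± 0.47), and at −0.03 without RT day 1 replicate 1. With the block the naive and homing list moved from adjusted p = 0.239 to 0.0173 at the preset correlation (0.423 with an estimated correlation).

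Green Treg-like cells of irradiated tumours carried more of the p53 targets Ccng1, Cdkn1a and Phlda3. Ccng1 stood at 403 ± 76.1 CPM in 3 irradiated and 100.0 ± 18.3 CPM in 5 unirradiated pools (SD), a log2 fold change of 2.11 ± 0.25 (SE), Cdkn1a at 288 ± 58.8 against 87.4 ± 56.1 CPM (1.63 ± 0.31) and Phlda3 at 44.1 ± 25.4 against 0.446 ± 0.997 CPM. The irradiated sums were RT day 1 replicates 1 and 2 (5 and 39 cells) and RT day 3 replicate 1 (7 cells). The NT day 1 sums held 6 and 45 cells. No sum of RT with FTY720 held enough cells, so the FTY720 stratum added nothing to the radiation contrast. RT and NT at day 3 were in different wells. Of 7992 genes, 5 rose and none fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), the others being Exoc4 and the gene model Gm42047, which the naming rule leaves out and which was chosen after its values were seen. Of the p53 targets 3 of 21 rose (9 adjusted over the list alone), with a median of 0.74 and adjusted p = 0.0882 with an estimated correlation. Cell cycle genes had a median of −2.22, with 0 of 15 passing (6 lower adjusted over the list alone; adjusted p = 0.166 with an estimated correlation). The count was 1 without NT day 1 replicate 1, 3 without NT day 1 replicate 2, NT day 3 replicate 1 or FTY720 replicate 2, and 10 without NT day 3 replicate 2. Ccng1 passed in every fit with a pool left out, Cdkn1a in 1 of 8 (without RT day 1 replicate 1), Phlda3 in 2 of 7 (without FTY720 replicate 2 or RT day 1 replicate 1) and Exoc4 in 4 of 8. The count was 13 with a replicate block, 39 with a term for the well and 0 with the label colours. Within wells at day 1 (n = 2 each), 3 genes rose and 1 fell: Ccng1 (2.18 ± 0.32), Exoc4 (1.89 ± 0.29) and Rps19, again outside the rule, were higher and Rsad2, the antiviral enzyme viperin, was lower (−2.90 ± 0.49). That count was 39 with a replicate block, 7 and 1 without replicates 1 and 2 of NT, and 2 without either RT replicate. Ccng1 and Exoc4 did not pass without replicate 2 of NT or of RT, and Rsad2 passed without NT replicate 1 alone. Interferon-stimulated genes had a median of −0.64 there (1 of 25 lower, 5 adjusted over the list alone; adjusted p = 0.322 with an estimated correlation).

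Red Treg-like cells of irradiated tumours carried more Gzmb and Ifi204. Gzmb stood at 5105 ± 1625 CPM in 6 irradiated and 1933 ± 273 CPM in 5 unirradiated pools (SD), a log2 fold change of 1.29 ± 0.19 (SE), and Ifi204 at 53.3 ± 43.0 against 3.48 ± 2.68 CPM. Of 7151 genes, 17 rose and 2 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the interferon-stimulated genes 4 of 26 rose (17 adjusted over the list alone), with a median of 1.12 and adjusted p = 0.147 with an estimated correlation. Examples are Zbp1 (0.89 ± 0.17) and Ifi27l2a, an interferon-inducible gene (1.16 ± 0.20). Cdkn1a rose (1.36 ± 0.25), 1 of 17 p53 targets (median 0.13; adjusted p = 0.326 with an estimated correlation), and Kif11, a mitotic kinesin, fell (−2.67 ± 0.43), as did the TCR segment Trav17, which is outside the naming rule and was chosen after its values were seen. The count was 0 without RT day 1 replicate 1 (edgeR; 503 genes had an unadjusted p below 0.05 with all pools and DESeq2 called 96), 9 and 4 without replicates 1 and 2 of RT day 3, 97 and 9 without those of RT with FTY720, 7 and 41 without those of NT day 1, 10 and 2 without those of NT day 3 and 11 without FTY720 replicate 2. Gzmb did not pass without NT day 3 replicate 2 or RT day 1 replicate 1, Ifi204 without these or RT day 3 replicate 2, and Kif11 without these 2 or NT day 1 replicate 1. Zbp1 and Cdkn1a did not pass in 8 of 11 such fits and Ifi27l2a in 7. The count was 30 with HTODemux, 1 with the label colours and 0 with a term for the well. Within wells at day 1 edgeR called 0 genes, DESeq2 2, and edgeR 2 with a replicate block. There 174 genes had an unadjusted p below 0.05 by edgeR, fewer than chance alone would give.

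At day 3, CD8-like cells of both colours from irradiated tumours carried more interferon-stimulated genes and Gzmb than those from unirradiated tumours. Isg15 stood at 1099 ± 85.4 against 158 ± 31.3 CPM (SD, n = 2 pools each; log2 2.81 ± 0.44 SE), Mx1, an antiviral GTPase, at 391 ± 34.0 against 60.1 ± 10.7 CPM (2.71 ± 0.17) and Gzmb at 3418 ± 1287 against 660 ± 109 CPM (2.37 ± 0.30). Of 10292 genes, 402 rose and 197 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the interferon-stimulated genes 23 of 25 rose and the rest did not pass (25 adjusted over the list alone), with a median of 2.06 and a camera call that held with an estimated correlation. Irf7, the regulator of type I interferon production (2.06 ± 0.15), and Cxcl10, a ligand of CXCR3 (4.37 ± 0.84), were among them. Of the p53 targets 2 of 23 rose (4 adjusted over the list alone; median 0.21; adjusted p = 0.727 with an estimated correlation), Cdkn1a (1.58 ± 0.27) and Trp53inp1, a p53-induced stress protein gene (0.87 ± 0.23). Of the cytotoxic genes 2 of 19 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.674), with the chemokine gene Xcl1 (−4.20 ± 0.70) and Gzmc (−3.45 ± 0.78) lower. Zfp683, the residency transcription factor Hobit (−3.15 ± 0.40), and Itga1, a collagen-binding integrin (−1.13 ± 0.15), fell, and Hif1a rose from 440 ± 62.3 to 1293 ± 124 CPM. Of the IL2 and STAT5 genes 3 of 10 rose (4 adjusted over the list alone; adjusted p = 0.348 with an estimated correlation). The macrophage marker Cd68 was higher (1.52 ± 0.40), 1 of 2 that rose among 12 myeloid genes (camera adjusted p = 0.492). Cluster 0 held 52.5% and the interferon-led cluster 13 held 21.3% of CD8-like cells in RT day 3, against 37.4% in cluster 0 and 29.0% in cluster 5 in NT day 3. These changes can include shifts between clusters. The count was 324 and 291 without replicates 1 and 2 of NT, and 342 and 396 without those of RT. In these 4 fits Isg15, Cxcl10, Xcl1 and Cd68 did not pass. Trp53inp1 passed in the one without NT replicate 2 and Gzmc in those without an NT replicate, and Mx1, Gzmb, Irf7, Cdkn1a, Hif1a, Zfp683 and Itga1 passed in each. RT and NT at day 3 were run in different wells. FTY720 against NT, across the same wells without radiation, gave 1 gene and an interferon list median of 0.608.

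Treg-like cells of both colours at day 3 carried more Gzmb after irradiation, at 5636 ± 968 against 1426 ± 103 CPM (SD, n = 2 pools each; 1.99 ± 0.27 SE), and more Irf7, at 807 ± 149 against 167 ± 5.50 CPM. In all 31 genes rose and 7 fell of 8269 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the interferon-stimulated genes 6 of 26 rose (17 adjusted over the list alone), with a median of 1.86 and adjusted p = 0.133 with an estimated correlation, among them Bst2, which encodes the antiviral tether tetherin (2.07 ± 0.27), and Gbp2, a guanylate-binding protein gene (1.87 ± 0.38). Of the genes that fell, Insig1 (−2.14 ± 0.42) and Fdft1 (−1.78 ± 0.38) act in cholesterol synthesis. These pools too were in different wells. Clusters 11 and 8 held 60.8% and 21.5% of Treg-like cells in NT day 3 and 31.4% and 57.1% in RT day 3. These changes can include shifts between clusters. The count was 0 by edgeR without either NT replicate (839 genes had an unadjusted p below 0.05 with all pools and DESeq2 called 119), and 16 without RT replicate 1. Insig1 and Fdft1 passed in none of the 4 fits with a pool left out, and Gbp2 passed in the one without RT replicate 2. The count was 20 with HTODemux.

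FTY720 was tested at day 3 as the mean over irradiated and unirradiated pools, of which the unirradiated part crosses wells. In Treg-like cells edgeR called 0 genes (482 at an unadjusted p below 0.05; DESeq2 0), and 2 with a replicate block. In CD8-like cells edgeR called 0 (829 at an unadjusted p below 0.05; DESeq2 13), 4 with a replicate block, 7 and 5 without replicates 1 and 2 of FTY720, and 1 without RT day 3 replicate 2 or RT with FTY720 replicate 1 (n = 4 pools against 4). S1pr1, a target receptor of FTY720, gave 0.32 ± 0.22 in CD8-like and −0.58 ± 0.65 in Treg-like cells, and Ccr7 1.61 ± 0.58 in Treg-like cells, none past the threshold. No member of a list passed. The calls at the preset correlation were lost with an estimated correlation, in CD8-like cells for early activation, naive and homing, migration receptor and myeloid genes (adjusted p = 0.327 each), cell cycle and hypoxia and glycolysis genes (0.577 each) and interferon-stimulated genes, and in Treg-like cells for migration receptors and interferon-stimulated genes. The interferon list had medians of 0.28 in CD8-like and −0.26 in Treg-like cells, with adjusted p = 0.608 and 0.895 with an estimated correlation, and migration receptors −0.23 in Treg-like cells (2 lower adjusted over the list alone; adjusted p = 0.719 with an estimated correlation). The myeloid list had a median of −1.69 in CD8-like cells (adjusted p = 0.327 with an estimated correlation). RT with FTY720 against RT, within wells, gave 8 genes in CD8-like (945 at an unadjusted p below 0.05), 6 of them mitochondrial genes that were lower, and by edgeR 0 in Treg-like cells (689). FTY720 against NT, across wells, gave 1 gene in CD8-like cells (669 at an unadjusted p below 0.05), the TCR segment Trbj2-7, which is outside the naming rule and was chosen after its values were seen.

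In the FTY720 wells, FTY720-treated pools with and without radiation shared a well. There, CD8-like cells of irradiated tumours carried more Cdkn1a, Pdcd1 and Mx1 and less of the replication helicase genes Mcm2, Mcm3 and Mcm5. This comparison and that of red cells at day 1 were added after the data were seen. Cdkn1a stood at 104 ± 10.0 against 12.3 ± 7.08 CPM (SD, n = 2 pools each; log2 2.85 ± 0.36 SE), Pdcd1 at 623 ± 104 against 293 ± 7.47 CPM and Hif1a at 1316 ± 1.75 against 424 ± 118 CPM. Of 10292 genes, 292 rose and 234 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of the interferon-stimulated genes 11 of 25 rose (20 adjusted over the list alone), with a median of 1.43 and adjusted p = 0.0688 with an estimated correlation, Mx1 (1.85 ± 0.19) and Irf7 (1.48 ± 0.16) among them. Of the cytotoxic genes 5 of 19 rose (10 higher and 2 lower adjusted over the list alone; median 0.82; adjusted p = 0.0688 with an estimated correlation), with Gzmb (1.34 ± 0.30), Gzmc (5.72 ± 1.14) and Ccl4 (2.38 ± 0.46). Of the exhaustion genes 4 of 15 rose (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.351 with an estimated correlation): Pdcd1 (1.08 ± 0.19), Lag3 (1.01 ± 0.23) and Havcr2, the receptor TIM-3 (1.36 ± 0.31), were among them. Of the cell cycle genes 5 of 23 fell (7 adjusted over the list alone; median −1.34; adjusted p = 0.351 with an estimated correlation), including Mcm2 (−1.24 ± 0.21), Mcm3 (−1.34 ± 0.21) and Mcm5 (−1.58 ± 0.27), and that median was 1.18 without FTY720 replicate 2. Of the p53 targets 3 of 23 rose (5 adjusted over the list alone; adjusted p = 0.340 with an estimated correlation). Cd68 was higher (2.24 ± 0.58) and Ighm lower (−2.09 ± 0.46). Clusters 0, 13 and 5 held 50%, 22.4% and 7.89% of CD8-like cells of irradiated tumours and 26.8%, 7.04% and 43.7% of those with FTY720 alone. These changes can include shifts between clusters. The count was 238 without RT with FTY720 replicate 1 and 151 with HTODemux. In the 4 fits with a pool left out Gzmb, Gzmc and Cd68 did not pass. The only pass came without RT with FTY720 replicate 2 for Lag3 and Havcr2, without RT with FTY720 replicate 1 for Ccl4 and without FTY720 replicate 2 for Ighm. Cdkn1a, Pdcd1, Hif1a, Mx1, Irf7, Mcm2, Mcm3 and Mcm5 passed in each. In Treg-like cells 7 genes rose and 8 fell. There clusters 11 and 8 held 61.3% and 25.8% of cells with FTY720 alone and 39.1% and 43.5% of cells of irradiated tumours. Gzmb stood at 5468 ± 914 against 1473 ± 637 CPM, and Ifi211, an interferon-inducible gene, at 338 ± 109 against 26.7 ± 14.0 CPM. Ccl5, a chemokine gene, stood at 46.6 ± 0.289 against 586 ± 83.4 CPM. Of the interferon list 2 of 26 rose (10 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation), and of 14 dissociation and heat shock genes Junb and Zfp36 fell (−1.60 ± 0.25 and −1.45 ± 0.26; adjusted p = 0.354 with an estimated correlation). This Treg-like count was 0 by edgeR without FTY720 replicate 1 (904 genes had an unadjusted p below 0.05 with all pools and DESeq2 called 81), 2 without FTY720 replicate 2, 40 and 27 without RT with FTY720 replicates 1 and 2, and 0 with at least 10 cells per sum. Gzmb did not pass without FTY720 replicate 1, Ifi211 without either FTY720 replicate, and Ccl5 in any of the 4 fits. The only pass came without RT with FTY720 replicate 1 for Junb and replicate 2 for Zfp36.

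**Figure D4:**
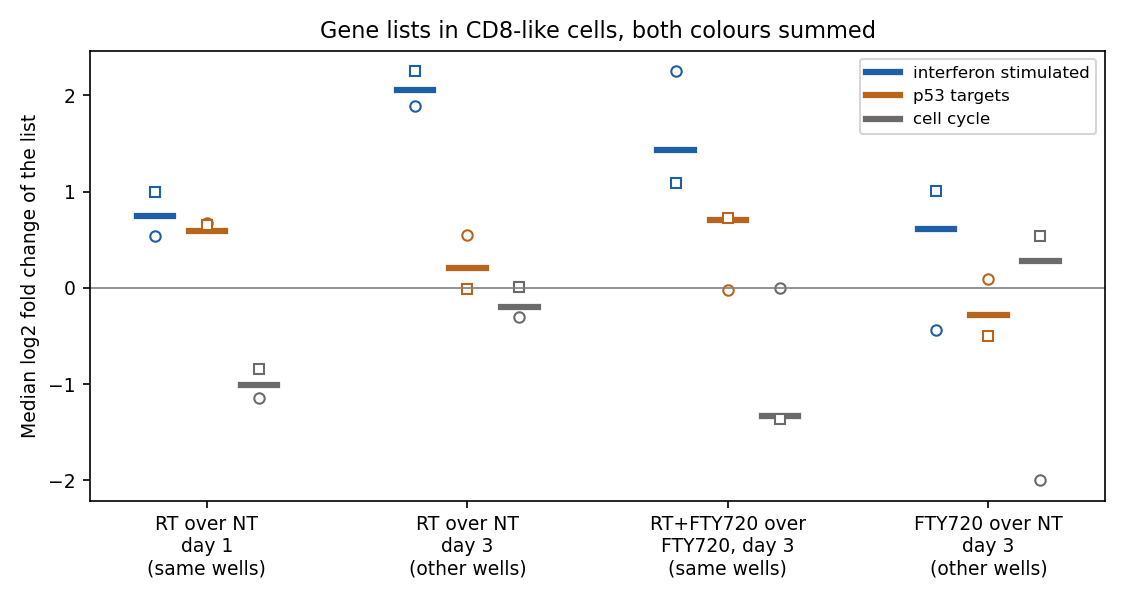
Median log2 fold change (vertical axis) of gene lists in CD8-like cells, both colours summed, for each radiation contrast and FTY720 (horizontal axis), where bars are the fitted median and the open circle and square are replicates 1 and 2 alone. The interferon list stands at 2.06 for RT against NT at day 3 and at 1.43 for RT with FTY720 against FTY720.

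Tests of the difference between radiation effects compared the days. In CD8-like cells the effect differed between day 3 and day 1 for 121 genes, 57 with a higher and 64 with a lower effect at day 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). Of 25 interferon-stimulated genes 6 had a higher effect at day 3 (14 adjusted over the list alone), with a median difference of 1.35, as for Irf7 (2.06 against 0.70) and Ifi27l2a (difference 1.78). Phlda3 had an effect of 4.00 at day 1 and −0.25 at day 3, and Cdkn1a showed no difference past the threshold (−0.51, adjusted p = 0.632). These day 3 effects cross wells. Taking the day 3 effect within wells under FTY720, 51 genes differed from day 1 (27 higher and 24 lower), Hif1a among them (difference 1.45), with an effect of 3.58 for Phlda3 (difference −0.42, adjusted p = 0.999), a difference of 0.78 for Irf7 (adjusted p = 0.120) and 1 interferon-stimulated gene (6 adjusted over the list alone). In Treg-like cells edgeR called 0 genes for either difference (354 and 544 at an unadjusted p below 0.05). The 354 are fewer than chance alone would give. Between colours over the strata, the CD8-like radiation effects gave 0 genes by edgeR (577 at an unadjusted p below 0.05), and the Cdkn1a effect was lower in red by 3.05 on the log2 scale with adjusted p = 0.0896. In Treg-like cells 8 genes differed, of which 4 are TCR segments, whose counts can follow the clones sampled (not tested), and 1 is Rps19. Ccng1 (−1.72) and Exoc4 (−1.42) had a smaller effect in red cells and Gem, a small GTPase gene (2.95), a larger one. At day 1 alone edgeR called 0 genes for the difference between colours in either class (118 in CD8-like and 221 in Treg-like cells at an unadjusted p below 0.05).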

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

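The tests of wells, of radiation within wells and of the number of cells were chosen after the result was seen, as were the difference between day 3 with FTY720 and day 1 and the alternative without the mixed clusters. The tests of colour names, dissociation, doublets, mixing of colours and the splits of samples were set before.

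Interferon-stimulated genes were higher after radiation at day 3 in CD8-like cells, by a list median of 2.06, in a comparison across wells. A difference between wells was argued against as the whole cause: FTY720 against NT, which crosses the same wells without radiation, gave a median of 0.608 (−0.44 and 1.00 in the 2 replicates). Within wells, radiation under FTY720 gave 1.43 (2.25 and 1.09), which the radiation named in the design may account for. A part of about the size of the first value remains open as a well or FTY720 effect.

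Early activation genes were higher in red than in green CD8-like cells, by a list median of 1.28. Exchanged colours in the replicate 2 wells were argued against, since the colour differences of replicates 1 and 2 correlated positively across genes (r = 0.386), where an exchange would make them negative. Dissociation stress would raise its own list alike, which stood at 0.13 (0.129). Leaving out the cells with 2 or more beta chains left the median at 1.27. These were 90 cells of all classes, 3.29% of those kept, so this cannot exclude doublets of other kinds. A candidate explanation is recent antigen contact of cells arriving from the node, which no value here tests.

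Cdkn1a was high in red as well as green CD8-like cells of RT day 1 replicate 1, with 6.73 on the log2(CPM + 1) scale in red cells against 5.57 in the next irradiated pool, far from the others. Chance marks about 1 in 20 groups of samples as having such a distant sample, and 31 groups were tested, with 6 found. A low number of cells was argued against, since the pool held 86 red CD8-like cells, against 13 to 101 in the other irradiated pools (median 21). Mixing of red and green cells in that pool may contribute and stays open: its signed red against green difference over genes called without it was 0.216, inside the 0.115 to 0.946 of the other pools (median 0.400). In the same pool Isg15 was lowest in green CD8-like cells, at 6.22 against 9.08 in the next pool.

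The other distant samples concern TCR clones and small numbers of cells. The clonal pair probability was 8.77% in red cells of RT with FTY720 replicate 1 (next 2.35%), 2.96% in green cells of RT with FTY720 replicate 2 (next 0.866%) and 1.28% in green cells of FTY720 replicate 1 (next 0.548%). Red cells with a clone in green cells reached 5.26% in RT with FTY720 replicate 1 (1 of 19 cells; next 1.54%).

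Radiation effects differed between groups by a test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg). In CD8-like cells 121 genes differed between day 3 and day 1, 51 between day 3 with FTY720 and day 1, and 5 between day 3 with and without FTY720 (Sema6d, Itga1 and, outside the naming rule and chosen after their values were seen, mt-Cytb, mt-Nd1 and mt-Nd4l). Phlda3 differed by −4.25 and Irf7 by 1.35 between day 3 and day 1, where the day 3 effects cross wells. Within wells, between day 3 with FTY720 and day 1, they differed by −0.42 and 0.78 (adjusted p = 0.999 and 0.120). In Treg-like cells 3 genes differed between day 3 with and without FTY720, Ctla2a (−3.31), Zfp36 (−2.21) and Junb (−2.12), and 8 between red and green cells over the strata, 4 of them TCR segments, with Ccng1 at −1.72 and Gem at 2.95.

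For red against green the pool-wise exchange of colours was repeated in 60 splits, the real one included. The real split gave the most genes in Treg-like cells (166, highest other split 22), CD8-like cells (751, highest other 300) and CD4 conventional-like cells (17, highest other 5). In each, 1 split of 60 was as large, the real one. That share of 0.0167 is below 0.05 and the smallest that 60 splits can give. It argues against chance in each class without excluding it. For radiation over the strata, 60 splits that ignore the wells again gave 1 split as large, the real one, in each of the following. These were red Treg-like (19, highest other 3), green CD8-like (278, highest other 193) and red CD8-like cells (68, highest other 5). Since these splits treat pools of the same and of different wells alike, they cannot exclude chance or a difference between wells. Splits that parted the pools of one replicate number within each stratum, as the real one does (22, 18 and 18), were also taken. At day 3 without FTY720 such pools lie in different wells. These splits reached 2 in red Treg-like, 193 in green CD8-like and 5 in red CD8-like cells, and 18 are too few for a share below 0.05. With a term for the well edgeR called 0, 10 and 0 genes (503, 1469 and 846 at an unadjusted p below 0.05 and 96, 613 and 262 by DESeq2, without that term). Too few splits for a share below 0.05 were possible for green Treg-like cells (18 splits, 2 as large, real 5, highest other 6) and for FTY720 (18 splits each, 18 as large, real 0, highest other 3 in Treg-like and 5 in CD8-like cells, where edgeR gave 482 and 829 genes at an unadjusted p below 0.05 and DESeq2 called 0 and 13).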

How the results depend on the processing

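The alternatives without the mixed clusters, with the label colours and for radiation in red cells at day 1 or under FTY720 were chosen after seeing the data, and the exchange of HTODemux with its alternative after seeing the hashtag counts. The sums of 8 to 23 cells in the day 3 RT and FTY720 wells limit what could be called in Treg-like cells, where few genes were recovered at 2-fold in simulated data for radiation with FTY720 (8.20%, of 4-fold 37.5%) and radiation at day 3 (8.60% and 66.3%). Of the planned and added alternatives other than leaving out a pool, 104 of the counts and single values stayed within 1.5 times or on their side of the threshold, 91 counts moved, 5 values were weaker, 1 stronger and 4 reversed. Of the list medians 267 stayed, 29 moved and 10 reversed. For named genes that passed, 1368 values stayed, 437 were weaker and 50 reversed; for those that did not pass, 291 stayed, 47 passed and 2 reversed. When a pool was left out, 962 stayed and 433 were weaker of the former and 215 stayed, 11 passed and 1 reversed of the latter, and 214 list medians stayed, 12 moved and 1 reversed. The cause of a change was not tested except where a sentence states what the alternative removes or adds.

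Counts that moved by over 1.5 times are given with the comparison in brackets, where colour is red against green, strata is radiation over the 3 strata, day 1 is radiation at day 1, RT day 3 and RT with FTY720 are radiation at day 3 without and with FTY720, and Treg, CD8 and CD4 are the Treg-like, CD8-like and CD4 conventional-like cells. Without a filter on low counts, which adds genes to the test, the counts were 451 (colour Treg), 1245 (colour CD8), 114 (colour CD4), 51 (strata green Treg), 166 (strata red Treg), 913 (strata green CD8), 435 (strata red CD8), 34 (day 1 green Treg), 102 (day 1 green CD8), 198 (RT day 3 Treg), 924 (RT day 3 CD8), 23 (FTY720 Treg), 63 (FTY720 CD8), 50 (day 1 red Treg), 38 (day 1 red CD8), 124 (RT with FTY720 Treg) and 842 (RT with FTY720 CD8). DESeq2 called 39 (colour CD4), 96 (strata red Treg), 613 (strata green CD8), 262 (strata red CD8), 0 (day 1 green Treg), 13 (day 1 green CD8), 119 (RT day 3 Treg), 13 (FTY720 CD8), 2 (day 1 red Treg) and 81 (RT with FTY720 Treg). DESeq2 size factors in edgeR gave 3 (strata green Treg) and 1 (FTY720 CD8). With at least 10 cells per sum, which removes sums, the counts were 54 (colour Treg), 21 (strata green Treg), 12 (strata red Treg), 21 (day 1 green Treg), 2 (day 1 red Treg) and 0 (RT with FTY720 Treg). Marker gates in place of clusters gave 478 (colour CD8), 69 (colour CD4), 50 (strata red Treg), 140 (RT day 3 Treg) and 1039 (RT with FTY720 CD8). The HTODemux calls gave 40 (colour Treg), 4 (colour CD4), 30 (strata red Treg), 139 (strata green CD8), 3 (strata red CD8), 20 (RT day 3 Treg), 2 (FTY720 Treg), 3 (day 1 red Treg), 1 (day 1 red CD8), 8 (RT with FTY720 Treg) and 151 (RT with FTY720 CD8). Leaving out cells with 2 beta chains gave 98 (colour Treg), 32 (strata red CD8), 2 (day 1 green Treg) and 1 (FTY720 CD8). Leaving out the mixed clusters, which are led by p53 target, interferon and cell cycle genes, gave 98 (colour Treg), 16 (strata green CD8), 12 (strata red CD8), 3 (day 1 green CD8), 1 (FTY720 CD8) and 9 (RT with FTY720 Treg). The label colours gave 0 (colour Treg), 1 (colour CD8), 0 (colour CD4), 0 (strata green Treg), 1 (strata red Treg), 0 (strata green CD8), 149 (strata red CD8), 1 (day 1 green Treg), 0 (day 1 green CD8) and 1 (day 1 red Treg). Comparisons with a 0 above had, by edgeR with the reported settings, 1207 (colour Treg), 471 (colour CD4), 484 (strata green Treg), 1469 (strata green CD8), 315 (day 1 green CD8) and 904 (RT with FTY720 Treg) genes at an unadjusted p below 0.05. Green cells alone gave no value for FTY720 and for RT with FTY720 in Treg-like cells, since too few sums were left.

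The pairing by well mattered for a part of the counts. No replicate block for red against green gave 293 (colour Treg) and 4 (colour CD4). A replicate block gave 13 (strata green Treg), 39 (day 1 green Treg), 2 (FTY720 Treg), 4 (FTY720 CD8) and 2 (day 1 red Treg). The p-values below 0.05 without adjustment numbered 503 and 846 in the reported fits of strata red Treg and strata red CD8, where the well block gave 0 by edgeR. A replicate block by 10x well gave 39 (strata green Treg), 0 (strata red Treg), 10 (strata green CD8) and 0 (strata red CD8). Apart from these fits the choice of colours was varied: both colours summed gave 23 (strata green Treg), 350 (strata red CD8), 1 (day 1 green Treg), 16 (day 1 green CD8), 1 (day 1 red Treg) and 16 (day 1 red CD8). Green cells alone gave 118 (RT day 3 Treg), 283 (RT day 3 CD8) and 44 (RT with FTY720 CD8). The block also moved gene list calls at the preset correlation. With the well term, adjusted p moved in strata red CD8 for cell cycle (0.728 to 1.68e-15), p53 target (0.0979 to 0.00627), cytotoxic (0.117 to 0.0144), dissociation (0.280 to 0.000237), tumour effector Treg (0.0333 to 0.137) and hypoxia and glycolysis genes (0.0371 to 0.142), in strata green Treg for cytotoxic (0.468 to 0.00631) and hypoxia genes (0.0102 to 0.0736), and in strata red Treg for migration receptors (0.367 to 0.0111) and hypoxia genes (0.255 to 3.91e-08). With the replicate block it moved in strata green Treg for interferon genes (0.0379 to 0.186). None of the calls gained with a block held with an estimated correlation, at adjusted p of 0.0800 (cell cycle), 0.388 (p53 target and cytotoxic) and 0.196 (dissociation) in strata red CD8, 0.451 (cytotoxic) in strata green Treg, and 0.276 (migration receptors and hypoxia) in strata red Treg. Apart from these and the list calls given with the day 1 CD8-like results, the block changed no call of a list in the day 1 and strata fits.

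Leaving out each pool in turn gave ranges of 31 to 195 (colour Treg), 337 to 892 (colour CD8), 7 to 32 (colour CD4), 1 to 10 (strata green Treg), 0 to 97 (strata red Treg), 68 to 438 (strata green CD8), 20 to 139 (strata red CD8), 1 to 7 (day 1 green Treg), 0 to 9 (day 1 green CD8), 0 to 3 (day 1 red CD8), 0 to 30 (RT day 3 Treg), 291 to 396 (RT day 3 CD8), 0 to 7 (FTY720 CD8), 0 to 40 (RT with FTY720 Treg) and 238 to 446 (RT with FTY720 CD8) genes, and edgeR called 0 in each for FTY720 Treg (482 at an unadjusted p below 0.05 with all pools) and day 1 red Treg (174). The Treg-like share difference between colours ranged from 7.04 to 10.6 percentage points, that of radiation from −4.44 to 0.429 in green and from −1.52 to 5.15 in red cells, clone sharing from 0.445 to 0.923 points and the clonal pair difference from 0.258 to 1.03 points. Signs changed for the Treg-like shares as given above. They also changed in Cdkn1a of day 1 red CD8 without RT_D1 replicate 1 (−0.0332, range to 1.78). The cell cycle list median of RT with FTY720 CD8 did so without FTY720_D3 replicate 2 (1.18, range from −1.95).

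Among single values, the Treg-like share difference between colours was 7.70 points without the mixed clusters (exact permutation p = 0.0786) and −2.18 with the label colours. The radiation difference in the green Treg-like share became 2.58 without the mixed clusters and 2.84 with the label colours, and in the red share −3.03 with the label colours. Clone sharing was 0.489 points with at least 20 cells, 0.652 with alpha and beta chains together, 0.616 with Cell Ranger clonotypes and 0.287 with HTODemux, each no longer past 0.05. The clonal pair difference was 1.02 with the label colours (exact permutation p = 0.0366).

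With the label colours red against green log2 fold changes changed sign in Treg-like cells for Ccr7 (−1.10), Irf8 (−0.11), Klf3 (−0.33), Ccr4 (−0.28), Lag3 (0.76), Entpd1 (0.41), Fasl (0.38), Hspe1 (−0.11), Mettl1 (−0.63), Ramp3 (−1.40), Itih5 (0.54), Srgap3 (0.67) and Plek (0.47). In CD8-like cells they did for Egr2 (−0.58), Ccl3 (−0.63), Ccl1 (−1.60), Ifng (−0.13), Tnf (−0.17), Nr4a1 (−0.27), Nr4a3 (−0.30), Cd83 (−0.26), Tnfsf14 (−0.45), Nfkbid (−0.24), Cd160 (−0.46), Lag3 (−0.0149), Tcf7 (−0.13), Il7r (−0.0229), Bcl2 (0.17), Itga4 (0.37), Gzmd (0.77), Gzme (1.20), Gzmf (0.39), Cd244a (0.65), Cd38 (0.35), Oas1a (0.27), Oasl2 (0.66), Stat2 (0.23), Spp1 (1.47), Cd74 (−0.11), Ighm (0.40) and Pdcd1 (−0.14). In CD4 conventional-like cells they did for Tcf7 (−0.13), S1pr1 (−0.24), Icos (−0.35), Ctla4 (−0.26), Il6ra (−0.31), Fasl (0.41), Csf1 (0.31) and Plk2 (2.42). List medians did in Treg-like (naive and homing −0.23, exhaustion 0.18), CD8-like (early activation −0.28, exhaustion −0.12, cytotoxic −0.0769, interferon 0.33, naive and homing −0.0589) and CD4 conventional-like cells (cytotoxic 0.57). Exchanging the colour of 6 of the 12 pools mixes both directions, which the construction of this alternative explains. Elsewhere the sign changed for the Treg core list of colour Treg with HTODemux (−0.0293), S1pr1 of FTY720 CD8 with marker gates (−0.70), Oasl2 (0.00327) and the interferon list median (0.16) of colour CD8 without the mixed clusters, and Rsad2 of day 1 green Treg with both colours summed (0.88).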

Other observations

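Untreated tumours were compared between the collection times. NT day 3 against NT day 1 gave 11 genes in CD8-like cells (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05; n = 2 pools each; 648 at an unadjusted p below 0.05) and by edgeR 0 in Treg-like cells (371 at an unadjusted p below 0.05). The list medians in CD8-like cells were 0.09 for interferon-stimulated, 0.01 for p53 target and −0.79 for cell cycle genes. This comparison was chosen after the data were seen. With both colours summed, radiation at day 1 gave 16 genes in CD8-like and 1 in Treg-like cells, and 5 of 23 p53 targets and 2 of 25 interferon-stimulated genes rose in CD8-like cells.

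Genes with the largest changes in red CD4 conventional-like cells outside the lists included Il6ra, a chain of the interleukin-6 receptor (1.51 ± 0.23), Icos, a costimulatory receptor (0.69 ± 0.13), and Ets1, a lymphocyte transcription factor (0.64 ± 0.12), all higher, and Plk2, a stress-induced kinase (−3.26 ± 0.53), lower. In red CD8-like cells Cd83 (3.01 ± 0.36) and Tnfsf14, the ligand LIGHT (2.45 ± 0.36), were higher, and Spp1, which encodes osteopontin (−4.70 ± 0.74), was lower.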
